A study of Mus musculus with 2 samples.

How the data were processed

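MicroRNA sequencing was done on total RNA from the adrenal gland of male B6CASTF1/J mice aged 10 days, with inserts below 30 bases, per the labels. The labels give 1 group with 2 biological replicates, taken from 2 numbered biosamples with 1 library each. The authors deposited raw read counts per microRNA gene for each library, with no normalization and no pooling. The deposited readme names genome build mm10 and genome annotation M21; the aligner and the counting tool are not given in the sources used here. The deposited count tables have no header. They hold 3 count columns, read from their totals as unstranded, sense-strand and opposite-strand counts, and 4 leading entries for reads given to no gene.

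Reads on the sense strand were used. Replicate 1 had 2843734 sense counts out of 7503044 reads and replicate 2 had 3080062 out of 8907701, as shares 37.9% and 34.6%. Unmapped reads were 26.4% and 32.0%, reads mapping to several places 27.5% and 25.9%, and mapped reads outside microRNA genes 8.22% and 7.54%; these stayed out of the library totals. The deposited counts leave out reads that map to several places, so any reads that identical mature copies share are not in the levels given here. The genome build is that of C57BL/6J, and alleles of the cross were not separated here. With these totals, a gene without reads lies below 3 counts, or 1.055 CPM in replicate 1 and 0.974 CPM in replicate 2. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only.

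All 2202 gene identifiers matched the GENCODE M21 annotation, from which symbols, positions, host genes on the same strand and hairpin sequences were taken. CPM was computed as counts over the sense total of the library. The log2 ratio of replicate 2 over replicate 1 used an added 0.5 counts. Each of 27 gene lists, fixed with the tests before the data were examined, was described by its share of counts, its median CPM and its median log2 ratio. The medians were set against 10000 random lists of the same size, and for ratios these were matched on mean expression in 10 bins; a ratio was taken to stand apart below the 2.5th or above the 97.5th percentile. Genes with at least 20 reads over both libraries were compared between the libraries by a two-sided exact binomial test with Benjamini-Hochberg adjustment and a threshold of 0.05. With a single group, no test between groups could be made. The counts of the 376 tested genes differed by far more than sampling noise between the libraries (chi-square of 342470 on 375 degrees of freedom), so the tables are not a single library deposited under 2 names. That the libraries are separate biological replicates rests on the labels.

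The text names the 20 genes with the highest mean CPM, up to 4 highest genes of each list, fixed markers of other cell types whatever their level, and the 5 largest log2 ratios in each direction among genes past the test with at least 100 reads. Mirlet7e, Mir98, Mir654, Mir24-1, Mir145b, Mir194-1, Mir199a-1, Mir199a-2, Mir199b, Mir450-1, Mir148a, Mir101b and Mir802 fall outside this rule and were chosen after their values were seen. Dispersion was estimated with edgeR 4.0.16 using TMM factors of 0.978 and 1.02, and with DESeq2 1.42.0, under R 4.3.3. Other steps used Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6. The binomial test was tested on simulated data for replicate 2 against replicate 1, over 373 genes. It recovered 84.9% of genes changed by 1 log2 unit and 99.0% of those changed by 2, and called 3.93% of unchanged genes. The simulated counts held counting error only, and the test was given the true shift in composition, which is unknown for the real libraries. These rates therefore do not cover the spread between replicates beyond counting error. For the estimate of dispersion over 376 genes, simulated coefficients of 0.2 and 0.5 came back as 0.210 and 0.455.

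Alternatives covered the scaling of the libraries (TMM, DESeq2 size factors, totals with unplaced reads, totals without the highest gene), unstranded counts, count filters, pseudocounts, and each replicate left out. A correction for hairpin GC content, a split of the multi-copy lists by shared 20-base words, and the opposite-strand share without overlapping genes were added after seeing the data. Mature arms and signal tracks were not used here.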

Results

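Small RNA below 30 bases was sequenced from the adrenal glands of 10-day-old male B6CASTF1/J mice, the first-generation cross of C57BL/6J with the wild-derived CAST/EiJ strain. The labels describe 1 group of 2 biological replicates, each from a separately numbered biosample. No treatment or second tissue was included, so the data give the microRNA reads placed at 1 locus in these adrenal samples and their spread between the replicates. RNA from another tissue, such as liver, was not excluded. Reads counted on the strand of a microRNA gene numbered 2843734 in replicate 1 and 3080062 in replicate 2. All levels are CPM, counts scaled to these totals, given as mean ± SD over both replicates, and positions are on mm10. Because both samples carry the same donor label, which names the strain, the SD measures the spread between these samples only.

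A small number of genes held most of the counted microRNA reads, which are those placed at 1 locus. The ranks below leave out reads mapping to several places. Mir378a, which lies in an intron of Ppargc1b (chromosome 18, 61397835 to 61397900) and is tied to mitochondrial metabolism, had the highest mean level, at 87019 ± 4408 CPM (SD, n = 2). Mirlet7g, in an intron of Wdr82 (chromosome 9, 106178840 to 106178927), followed at 72075 ± 8817 CPM (SD, n = 2). Mir126a, the endothelial microRNA gene within Egfl7 (chromosome 2, 26591357 to 26591429), had 64756 ± 27586 CPM (SD, n = 2). Mir122, the main microRNA of hepatocytes (chromosome 18, 65248861 to 65248926, in an exon of a long intergenic noncoding RNA), had 63637 ± 48385 CPM (SD, n = 2). The wide error of Mir122 came from 29424 CPM in replicate 1 against 97850 CPM in replicate 2. Mir378a led by its mean only. Mir126a was above it in replicate 1, at 84262.5 against 83902.0 CPM, and Mir122 in replicate 2, where Mir378a had 90136.2 CPM. The next genes were Mirlet7b at 48370 ± 14027 CPM, Mirlet7i at 45445 ± 2426 CPM and Mir375 at 34264 ± 168 CPM. Mir143 of smooth muscle, at 33823 ± 5041 CPM, the X-linked Mir322, at 27157 ± 11740 CPM, and Mir139, from an intron of Pde2a, at 26736 ± 8395 CPM, completed the highest 10.

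The highest 10 genes together took 48.9% of the counts in replicate 1 (exact Clopper-Pearson 95% interval 48.9 to 49.0%) and 51.7% in replicate 2 (51.7 to 51.8%). Their mean was 50.3% ± 1.98 (SD, n = 2), and the highest 20 genes took 69.98% ± 0.433 (SD, n = 2). Of the 2202 annotated microRNA genes, 382 reached 2 CPM in both libraries. Ranks 11 to 20 held Mir10a of the Hoxb region, Mir22, Mir23b, Mirlet7d, Mir335 from an intron of the imprinted gene Mest, Mir26b, Mir127, Mir23a, Mir99a and Mir652. Their levels ran from 24671 ± 7723 CPM for Mir10a to 13120 ± 1820 CPM for Mir652. Intervals on shares, and the floor of 3 counts used for genes without reads, cover counting error only, since amplified reads are not independent molecules.

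**Figure D1:**
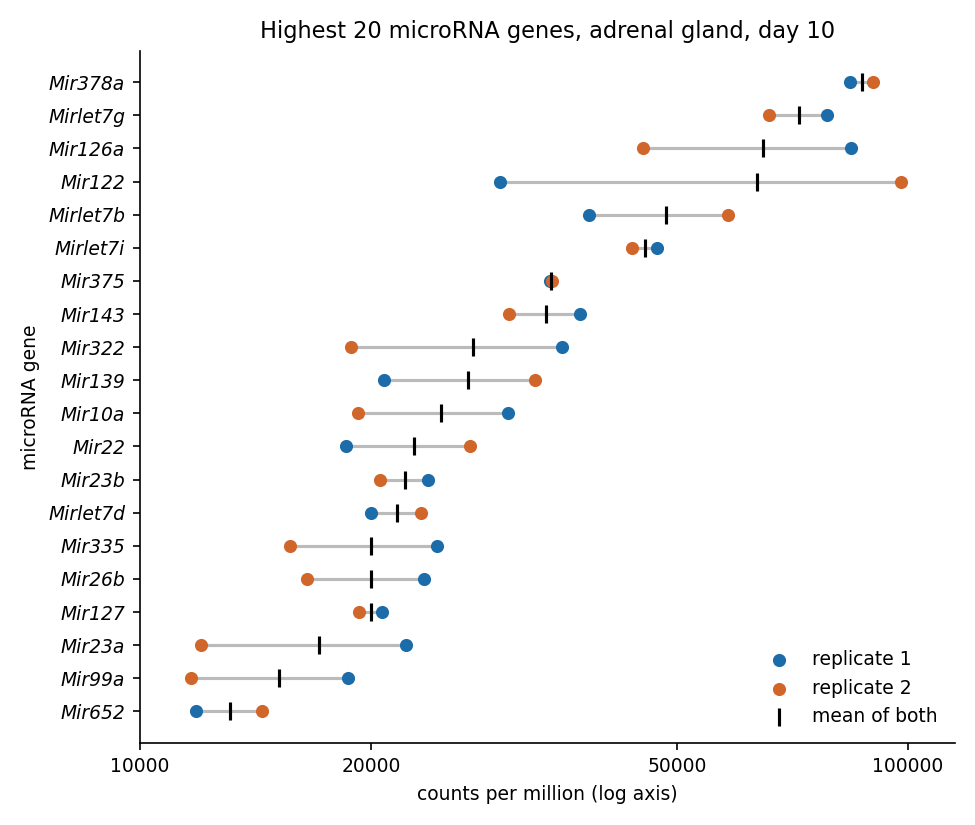
Level of the 20 microRNA genes with the highest mean, in CPM on a log axis, with 1 point per replicate, a grey line between them and a black mark at the mean. Mir375 differed least, at 34145 and 34383 CPM, and Mir122 spanned 29424 to 97850 CPM.

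The let-7 family, which represses growth and early developmental genes as tissues mature, held a large share of the counts. Its 12 genes took 20.0% of the counts in replicate 1 and 21.1% in replicate 2, a mean of 20.5% ± 0.742 (SD, n = 2). Mirlet7g, Mirlet7b, Mirlet7i and Mirlet7d supplied most of it, and Mirlet7e and Mir98 had 9200.0 and 4020 CPM. The list also holds multi-copy genes, whose shared reads were not counted. The family's share and the order of its members therefore apply only to reads placed at 1 locus. Of the 12 members, 6 were higher and 3 lower in replicate 2 by the exact binomial test, and 3 did not pass; the same numbers passed when adjusted over the list alone. The median log2 ratio of replicate 2 over replicate 1 was 0.16, at the 81.5th percentile of random lists matched on expression.

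Among other families, the miR-10 group, which includes Hox-linked genes, took 7.81% of the counts in replicate 1 and 5.42% in replicate 2 (mean 6.62% ± 1.69, SD, n = 2), led by Mir10a and Mir99a, and 0 of its 8 members were higher in replicate 2, 6 lower and 2 did not pass. The miR-23 clusters took 4.45% ± 0.967 with Mir23b at 22143 ± 2252 CPM (1 higher, 4 lower, 1 did not pass), and the miR-15 group, with Mir322, 4.08% ± 1.22 (5 higher, 6 lower, 2 did not pass). The miR-30 family took 2.61% ± 0.420 (3 higher, 2 lower, 1 did not pass), the growth-linked miR-17-92 clusters, led by Mir17 at 5621 ± 1622 CPM, 1.80% ± 0.357 (2 higher, 7 lower, 3 did not pass), and the miR-181 family 0.421% ± 0.0651 (1 higher, 3 lower, 2 did not pass). The miR-29 family, known to target collagen genes, took 0.118% ± 0.0296, led by Mir29a at 950 ± 229 CPM (0 higher, 2 lower, 2 did not pass). All these counts are from the exact binomial test and were the same adjusted over the list alone. The miR-26 family took 2.01% ± 0.478 (1 higher, 1 lower, 1 did not pass), and adjusted over the list alone 2 were higher and 1 lower. None of these 8 lists passed by its median log2 ratio, at the 12.1th percentile of matched random lists for the miR-10 group, the 6.98th for miR-17-92 and up to the 95.95th for miR-26. Each of the 8 lists holds multi-copy genes, whose shared reads were not counted. Shares and leading members therefore apply only to reads placed at 1 locus.

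The imprinted Dlk1-Dio3 cluster, whose microRNA genes are expressed from the maternal chromosome, took 8.16% of the counts in replicate 1 and 8.03% in replicate 2. The mean was 8.09% ± 0.0883 (SD, n = 2). All 50 listed genes lie on the plus strand of chromosome 12 between 109563692 and 109747960, and 47 of them reached 2 CPM in both libraries and 20 reads in sum. Mir127, which lies opposite Rtl1, was the highest at 19969 ± 989 CPM (SD, n = 2), followed by Mir411 at 11348 ± 3088 CPM, Mir379 at 8274 ± 2625 CPM and Mir541 at 6190 ± 324 CPM. In all, 13 genes of the cluster reached 1000 CPM, and Mir654 had no read in either library, which allows up to 1.055 and 0.974 CPM. The exact 95% intervals of the cluster's share, 8.12 to 8.19% and 8.00 to 8.06%, did not overlap. Of the single members, 17 were higher and 26 lower in replicate 2, 4 did not pass, and these counts also held when adjusted over the list alone. The median log2 ratio was -0.11, at the 16.2th percentile of matched random lists.

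**Figure D2:**
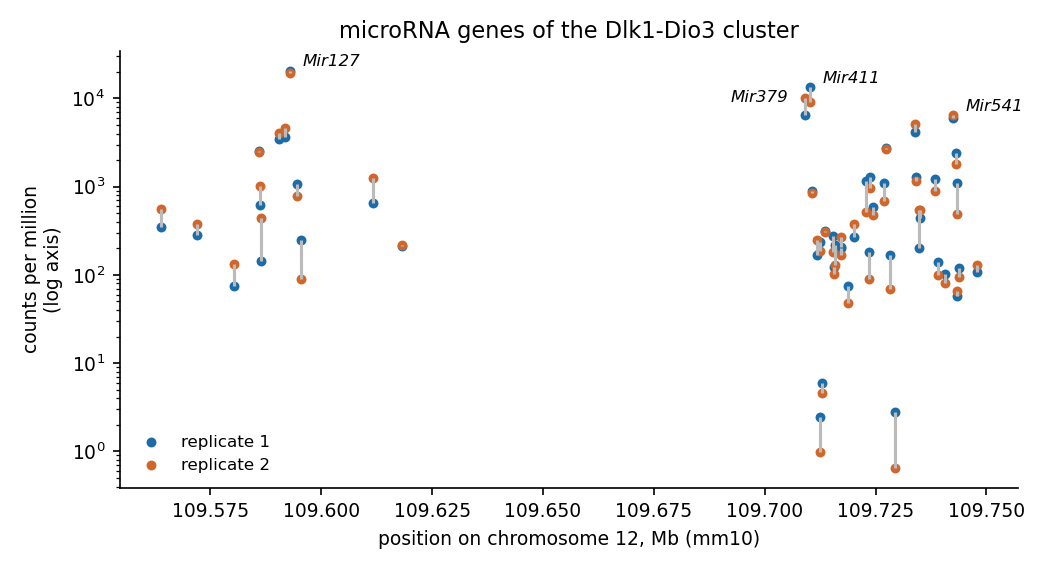
Level in CPM, on a log axis, of the Dlk1-Dio3 microRNA genes with a read, against their position on chromosome 12 in megabases. Points are the 2 replicates, joined by a grey line; Mir127 stands highest in the left part, and Mir411, Mir379 and Mir541 in the right part.

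At the imprinted Igf2-H19 locus, Mir483, in an intron of the fetal growth factor gene Igf2, had 817 ± 541 CPM (SD, n = 2). Mir675, which is processed from H19, had 11.8 ± 1.72 CPM. Mir483 was higher in replicate 2, with a log2 ratio of 1.47 and 1235 against 3694 reads (exact binomial test, Benjamini-Hochberg adjusted p = 5.63e-239). Mir675 had a log2 ratio of 0.29 and did not pass (exact binomial test, adjusted p = 0.474).

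Genes reported to respond to adrenocorticotropic hormone or to act in steroidogenesis held 4.85% and 4.65% of the counts, a mean of 4.75% ± 0.136 (SD, n = 2). Mir335 led the list at 20025 ± 6103 CPM, followed by Mir21a, a growth-associated gene at the Vmp1 locus, at 10226 ± 4747 CPM, and by Mir125a and Mir320 at 5050 ± 151 and 2329 ± 765 CPM. Of the 23 members tested, 9 were higher in replicate 2, 10 were lower and 4 did not pass, with the same counts adjusted over the list alone. Mir335 was lower in replicate 2, with a log2 ratio of -0.63, and Mir21a was higher, at 0.98. The median log2 ratio was 0.01 and turned to -0.06 with edgeR's TMM library sizes, at the 58.8th percentile of matched random lists in both cases.

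Neuronal and chromaffin genes, listed for the adrenal medulla, held 4.26% and 4.00% of the counts, a mean of 4.13% ± 0.187 (SD, n = 2). Most of this was Mir375, a neuroendocrine and islet microRNA gene (chromosome 1, 74900658 to 74900721). It stood at 34145 and 34383 CPM, with a log2 ratio of 0.01 that did not pass (exact binomial test, adjusted p = 0.159). Mir7b, another neuroendocrine microRNA gene, had 4196 ± 1521 CPM, Mir149 had 1175 ± 103 CPM, and Mir137, a neuronal gene, had 611 ± 218 CPM; all 3 were lower in replicate 2, with log2 ratios of -0.76, -0.18 and -0.74. Of the 17 members tested, 10 were lower, 3 were higher and 4 did not pass, and these counts also held when adjusted over the list alone. The median log2 ratio was -0.46, at the 2.79th percentile of matched random lists, which did not pass; it passed, at the 0.820th percentile, when only genes with at least 100 reads were kept. The neuronal genes Mir124a-1, Mir124a-3, Mir9-1 and Mir9-2 had no read in either library, but each has near-identical copies whose shared reads were not counted here.

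Most reads of the vessel and connective tissue lists came from 1 gene each, Mir126a and Mir143. Mir126a was lower in replicate 2, with a log2 ratio of -0.90, and with Mir126b the endothelial list held 8.43% of the counts in replicate 1 and 4.53% in replicate 2. Its mean was 6.48% ± 2.76 (SD, n = 2); Mir126b lies on the opposite strand of Mir126a, and counts made without regard to strand lost nearly all reads of both. The smooth muscle, pericyte and fibroblast list held 4.21% ± 0.0354 (SD, n = 2), led by Mir143 at 33823 CPM and Mir140, the cartilage-associated gene in Wwp2, at 4872 ± 4778 CPM. Mir145a, the neighbour of Mir143 on chromosome 18, had 1450 ± 350 CPM, and Mir214 had 1886 ± 287 CPM. Mir199b and Mir199a-2 had 56.4 and 17.6 CPM, and Mir145b and Mir199a-1 had no reads. Mir199a-1 and Mir199a-2 are listed multi-copy genes, whose shared reads were not counted here. Of the 6 members tested, 3 were higher, 2 were lower and 1 did not pass, also when adjusted over the list alone.

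Genes of other tissues differed in level between the libraries by different amounts and directions. The liver marker Mir122 took 2.94% of the counts in replicate 1 (95% interval 2.92 to 2.96%) and 9.79% in replicate 2 (9.75 to 9.82%), with a log2 ratio of 1.73. Mir206, a skeletal muscle gene, had 2112 ± 1687 CPM and a log2 ratio of 1.85, and Mir499, in an intron of Myh7b, had 12.01 ± 11.02 CPM and a log2 ratio of 2.18. In the striated muscle list, 2 of the 3 members tested were higher in replicate 2 and 1 did not pass, also when adjusted over the list alone, and the median log2 ratio of 1.85 lay at the 99.4th percentile of matched random lists. Mir133b, another muscle gene, had 2.62 ± 2.72 CPM. The erythroid genes Mir451a, at 400 ± 236 CPM, and Mir144, at 90.8 ± 63.6 CPM, were lower in replicate 2, with log2 ratios of -1.28 and -1.57. Mir486, the remaining erythroid gene, was higher, at 1.28, and the list's median of -1.28 lay at the 1.26th percentile. Among leukocyte genes, Mir150, a lymphocyte gene, was higher in replicate 2, with a log2 ratio of 1.43, while Mir142, expressed across blood cells, had 379 ± 16.1 CPM and a log2 ratio of -0.09 that did not pass (exact binomial test, adjusted p = 0.208). The erythroid list had 1 member higher and 2 lower, and the leukocyte list, at 0.241% ± 0.0484 (SD, n = 2), 3 higher, 0 lower and 2 that did not pass, with the same counts adjusted over the list alone.

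Mir378a made up most of the adipose list, which took 9.13% ± 0.635 of the counts (SD, n = 2). Of its 6 members, 4 were higher in replicate 2, 0 were lower and 2 did not pass, also when adjusted over the list alone; unstranded counts, in which Mir378a has no reads, gave 0.526%. Mir10a likewise made up most of the kidney and gut list, at 2.51% ± 0.762, while the kidney and gut marker Mir192 had 128 ± 27.2 CPM. Of the 4 members tested, 2 were higher, 1 was lower and 1 did not pass, and 2 were higher and 2 lower when adjusted over the list alone. The X-linked cluster of the testis took 0.00141% ± 0.000247, with 0 members higher, 1 lower and 1 that did not pass, also when adjusted over the list alone.

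**Figure D3:**
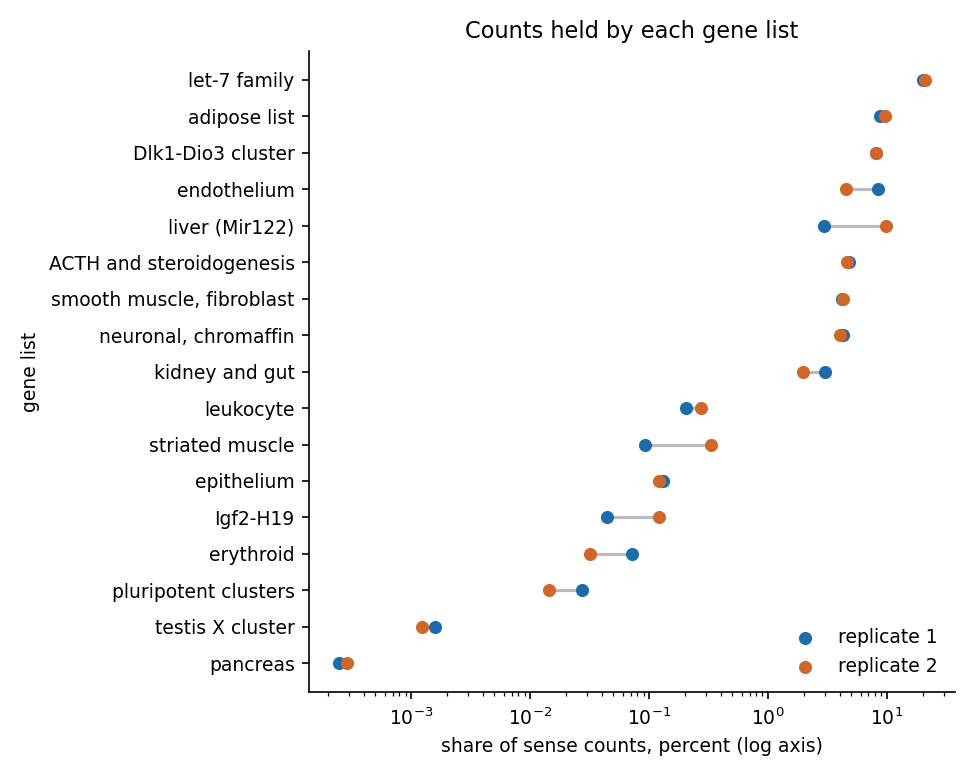
Share of the sense-strand counts, in percent on a log axis, held by 17 gene lists, with 1 point per replicate and a grey line between them. The let-7 list held 20.0 and 21.1%, and the striated muscle, liver and Igf2-H19 lists show the widest gaps between replicates.

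The replicates were then compared gene by gene. The expression of 376 genes with at least 20 reads correlated between the libraries with Pearson's r of 0.972 and Spearman's rho of 0.968 on the log2(CPM + 1) scale, across genes, which are not independent replicates. Under an exact two-sided binomial test with Benjamini-Hochberg adjustment, 255 of the 376 genes differed beyond counting error, 120 higher and 135 lower in replicate 2. Of these, 69 differed by at least 2-fold, 29 higher and 40 lower. The test compares these libraries and covers counting error only. The biological coefficient of variation estimated by edgeR was 0.389, and DESeq2's median gene-wise estimate was 0.219.

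Among genes with at least 100 reads that passed the exact binomial test, the 5 largest log2 ratios in favour of replicate 2 were those of Mir26a-2 at 3.08, Mir140 at 2.47, Mir298, which lies near the imprinted Gnas locus, at 2.41, Mir31 at 2.17 and Mir200b, an epithelial gene, at 2.02. The 5 in favour of replicate 1 were Mir153, from an intron of the secretory vesicle gene Ptprn2, at -3.90, Mir185 at -3.56, Mir301 at -2.21, Mir6538 at -2.06 and Mir30e at -1.84. The highest adjusted p of the 10 was 1.3e-27, that of Mir153 with 117 and 8 reads (exact binomial test). Mir26a-2 has a near-identical copy at another locus, so its 84 and 772 reads are only those that could be placed.

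**Figure D4:**
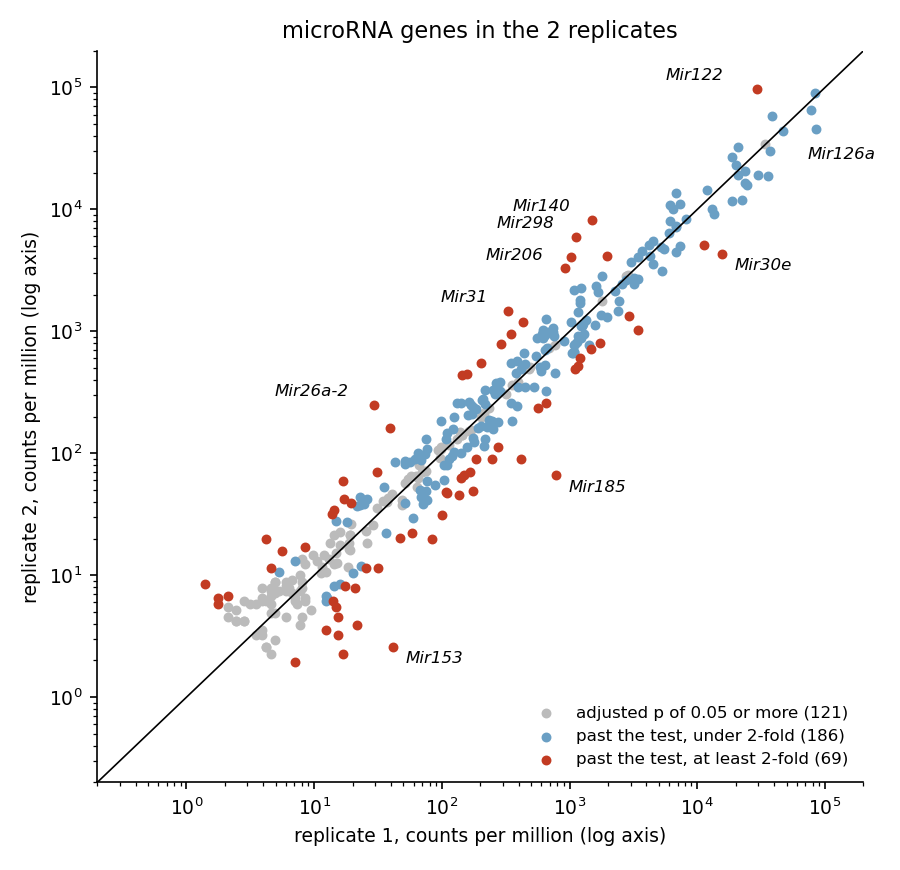
Level in CPM of each of the 376 tested genes in replicate 1 and replicate 2, both on log axes, with the line of equal levels. Grey points did not pass the exact binomial test, blue points passed at under 2-fold and the 69 red points passed at 2-fold or more; Mir122 lies far above the line and Mir185 far below it.

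Listed genes with near-identical copies elsewhere in the genome had a lower median count than the listed single-copy genes. Among all microRNA genes, both lists' medians lay at the 100th percentile of random lists. That comparison says little, since only 688 and 708 of the 2202 genes had a read in replicates 1 and 2. Against random lists of genes with a read, the multi-copy genes with a read still lay at the 99.94th percentile. The 52 listed multi-copy genes had a median of 55.7 CPM, against 2825 CPM for the 25 listed single-copy genes, a fold of 50.7. Within single libraries the fold was 88.0 in replicate 1 and 55.3 in replicate 2. The multi-copy list also holds families without a listed single-copy member, such as Mir9 and Mir124a, whose genes had at most 1 read per library. The fold is therefore not a comparison within families, and the part due to such genes was not separated. Mir29b-1 had 13.3 CPM and its cluster neighbour Mir29a 950 CPM. Mir24-1 had 66.4 CPM beside Mir23b at 22143 CPM, although Mir23b also shares a 20-base word with another hairpin. Of the 25 listed single-copy genes, 4 share such a word too, so their levels may also lack shared reads. In 16 of 19 genomic clusters that hold listed multi-copy genes and other genes, the multi-copy members had the lower median. The other genes of these clusters are neighbours, many of them from other families. Of 39 multi-copy genes tested, 13 were higher in replicate 2, 6 lower and 20 did not pass, and of 23 single-copy genes 7 were higher, 15 lower and 1 did not pass; the counts adjusted over the list alone were the same. When all genes with a read were split by a 20-base word shared with another hairpin, the fold turned to 0.165, that is, genes sharing a word had the higher median. Levels of single copies of these families are therefore uncertain here, and apply to reads placed at 1 locus.

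**Figure D5:**
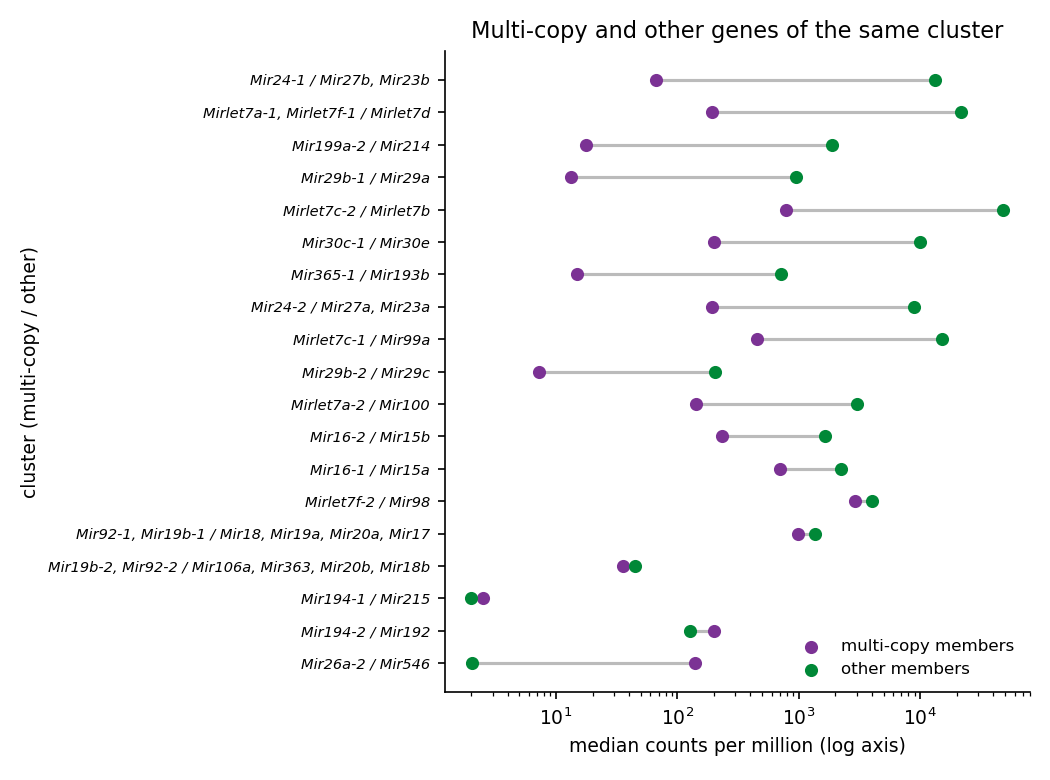
Median CPM, on a log axis, of multi-copy members (purple) and of the other members (green) of 19 genomic clusters, named on the vertical axis with the multi-copy genes before the slash. The purple point lies left of the green one in 16 clusters; the exceptions hold Mir194-1, Mir194-2 and Mir26a-2.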

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

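The values in this part are outside the counts compared above, and all tests of explanations here were chosen after the results were seen; the tests on multi-copy genes replaced an earlier one, the fold between the lists itself, which could not separate the explanations. Reads mapping to several places made up 27.5% of all reads in replicate 1 and 25.9% in replicate 2, a signal that no gene count includes. Reads on the strand opposite to a microRNA gene were also summed over the 2138 genes with no microRNA gene overlapping on the other strand. They numbered 250 in replicate 1 and 220 in replicate 2. Mir203, an epidermal gene, held 192 and 130 of these, beside 3238 and 2537 sense reads. Over all genes the opposite-strand share was 17.3% and 14.3%, because the reads of 64 genes that overlap another on the opposite strand are counted for both.

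The lower counts of the listed multi-copy genes than of the listed single-copy genes were weighed against loss of shared reads and against lower transcription. Their medians of 55.7 and 2825 CPM both lie at the 100th percentile of random lists. The lists cover partly different families, and the effect of this was not tested. Reads mapping to several places equalled 73.8% of the counted reads on average, more than the 25.7% of the counts that separate the lists, so there are enough such reads for their loss to be a candidate explanation. Their origin is not recorded, and they could also come from other repeated small RNA. Lower transcription of the multi-copy loci cannot be told apart from it: the other members of the same cluster, which are often made from 1 transcript, were higher by a median fold of 28.1 over 19 clusters, but the bootstrap range of 1.39 to 49.6 includes small folds.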

How the results depend on the processing

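Of the alternatives, the correction for hairpin GC content, the split of the fixed multi-copy lists by a shared word and the opposite-strand share without overlapping genes were chosen after seeing the data. Where no reason is given, the cause was not tested. Most settings left the median log2 ratios of the gene lists on the same side of the percentile limits: 165 values stayed, 5 passed only under an alternative and 2 no longer passed. The scalings of the libraries shift the log2 ratios of all genes alike and cannot move a percentile. Their values among the 165 therefore stayed by construction. The count of genes that differ kept within 1.5-fold in 8 of 9 alternatives. Of the mean CPM values of named genes under the alternatives, 630 moved by less than 1 SD and 126 by more. With 2 replicates, leaving 1 out moves a mean by less than 1 SD by construction, so those settings could not count as moved. A gene with a wide gap between replicates also has a wide limit. At this depth, a gene without reads lies below 1.055 CPM in replicate 1 and 0.974 CPM in replicate 2. No paired analysis was possible because there is a single group.

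Adding unplaced reads to the total lowered shares by construction: to 25.7% for the highest 10 genes, 10.5% for let-7, 3.39% for the miR-10 group, 0.920% for miR-17-92, 2.09% for the miR-15 group, 1.33% for miR-30, 0.0602% for miR-29, 1.03% for miR-26, 2.28% for the miR-23 clusters, 0.215% for miR-181, 4.14% for Dlk1-Dio3, 2.43% for steroidogenesis, 2.11% for neuronal and chromaffin, 3.32% for endothelial, 2.15% for smooth muscle, 0.123% for leukocyte, 0.0650% for epithelial, 1.28% for kidney and gut, 4.67% for adipose, 0.000138% for pancreas, 0.0108% for pluripotent, 0.000721% for testis, 0.577% for multi-copy and 13.7% for single-copy genes. A total without Mir378a raised shares by construction, to 22.5% for let-7, 8.87% for Dlk1-Dio3, 5.202% for steroidogenesis, 4.52% for neuronal and chromaffin, 4.61% for smooth muscle, 0.139% for epithelial, 10% for adipose and 29.4% for single-copy genes.

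Unstranded counts drop reads of overlapping genes and gave 24.1% for let-7, 2.22% for miR-17-92, 1.98% for miR-30, 2.49% for miR-26, 5.47% for the miR-23 clusters, 0.520% for miR-181, 9.10% for Dlk1-Dio3, 5.82% for steroidogenesis, 5.09% for neuronal and chromaffin, 0.000512% for endothelial, 5.19% for smooth muscle, 0.0113% for erythroid, 0.164% for epithelial, 0.526% for adipose, 0.000309% for pancreas, 0.00174% for testis, 1.34% for multi-copy and 30.7% for single-copy genes. With them, the percentile of the median CPM was 99.93 for miR-30, 99.01 for miR-29, 99.98 for miR-181, 71.0 for endothelial, 36.4 for erythroid, 99.88 for leukocyte, 87.8 for striated muscle, 99.76 for kidney and gut, 99.91 for adipose and 46.6 for testis genes.

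Random lists drawn from genes with a read gave percentiles of 96.3 for miR-17-92, 99.95 for the miR-15 group, 99.83 for miR-30, 83.9 for miR-29, 82.1 for miR-26, 99.89 for the miR-23 clusters, 98.1 for miR-181, 81.9 for Igf2-H19, 97.7 for neuronal and chromaffin, 95.9 for endothelial, 99.87 for smooth muscle, 81.8 for erythroid, 97.4 for leukocyte, 32.3 for striated muscle, 99.49 for liver, 88.5 for epithelial, 85.7 for kidney and gut, 99.01 for adipose, 1.89 for pancreas, 72.9 for pluripotent, 57.2 for testis and 99.94 for multi-copy genes. The mean in place of the median gave 98.9 for miR-29, 99.57 for miR-26, 99.99 for miR-181, 98.5 for erythroid, 99.85 for leukocyte, 81.2 for striated muscle, 100 for adipose, 92.0 for pluripotent and 2.68 for testis genes. Leaving out each replicate in turn gave percentiles of 99.99 to 99.99 for miR-30, 98.71 to 98.89 for miR-29, 99.91 to 99.92 for leukocyte, 95.69 to 97.53 for striated muscle, 99.55 to 99.99 for liver, 99.49 to 99.65 for kidney and gut, 99.97 to 99.98 for adipose, 31.03 to 77.11 for pancreas, 99.67 to 99.84 for pluripotent and 47.85 to 48.1 for testis genes, shares of 49.86 to 52.53% for the highest 10 genes, and folds of single-copy over multi-copy genes of 55.28 to 87.95.

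The median log2 ratio passed the percentile limits with no filter for the neuronal and chromaffin list (-0.46, percentile 2.29), the kidney and gut list (0.80, 97.62) and the single-copy list (-0.34, 2.04). With at least 100 reads the neuronal list passed (-0.56, 0.820) and the pluripotent list no longer did (-0.91, 3.63). The same held with the GC trend removed, at -0.49 (0.730) and -0.72 (3.25). A filter of at least 1 read in each library detected 613 genes, and 69 genes differed by at least 2-fold; both follow from the limit itself. The correlation was 0.989 without a filter and 0.960 at 100 reads, and the coefficient of variation 0.219 with DESeq2 and 0.384 at 100 reads. The fold of single-copy over multi-copy genes reversed to 0.165 when all genes with a read were split by a shared 20-base word. This split sets different families side by side (13.1 CPM over 142 genes against 2.15 CPM over 641), and the fixed lists do so in part. With unstranded counts the fold was 88.6. The opposite-strand share was 0.00984% at genes without an overlapping microRNA gene, against 15.8%. Across scalings, the part of the differing genes that was higher in replicate 2 ran from 43.5 to 49.8%, and 225 of the 255 genes also passed with the GC trend removed.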

Other observations

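All tests of explanations in this part were chosen after the results were seen. For the liver genes and for the clusters a further condition was added once the first value was known: a first reading on the 98.1th percentile alone, or on the correlation of 0.186 alone, would have passed. In the 40 genomic clusters with at least 2 genes of 100 reads or more, spaced by at most 10000 bases, the highest member exceeded the lowest by a median of 11.3-fold, and by over 10-fold in 20 clusters; in 9 of these the lowest member is a listed multi-copy gene, whose level is uncertain here. Mir322 had 27157 CPM and Mir450-1, from the same X-linked cluster, 17.6 CPM, although Mir450-1 also shares a 20-base word with another hairpin. Mir181c and Mir181d on chromosome 8 were close, at 1631 and 1553 CPM. Genes of clusters active in pluripotent cells were also present at low levels, with Mir294 at 65.7 ± 48.8 CPM and Mir293 at 58.8 ± 24.8 CPM (SD, n = 2). In that list, 5 of 7 members tested were lower in replicate 2 and 2 did not pass, with the same counts adjusted over the list alone; the median log2 ratio of -0.94 lay at the 1.20th percentile of matched random lists, and no longer passed at 100 reads or with the GC trend removed. The epithelial list was led by Mir203 at 981 ± 223 CPM, which was lower in replicate 2, with a log2 ratio of -0.47. With Mir200c at 75.9 ± 20.3 CPM and Mir205 at 30.3 ± 10.5 CPM among its lower members, the list took 0.127% ± 0.00705 of the counts and had 5 members higher in replicate 2, 1 lower and 1 that did not pass, also when adjusted over the list alone; its median log2 ratio of 0.72 lay at the 99.2th percentile. Genes of the pancreas list were at or below 2.34 CPM, the mean of Mir217, and none had enough reads for the test.

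The higher level of Mir122 in replicate 2, by 1.73 on the log2 scale, was set against scaling, hairpin GC content and RNA from liver. Scaling argues against itself as the cause, since the lowest log2 ratio over the scalings was 1.67. Removing the GC trend raised the ratio to 1.90, with a residual SD of 0.86 over genes. RNA from liver stays open: in a list of other liver-abundant genes the median log2 ratio of 0.66 over 7 genes lay at the 98.1th percentile, but several of these values had been seen when the list was written, 4 of the 7 are also in other tissue lists, and the other 3 had a median of -0.67 at the 7.92th percentile. Mir148a and Mir101b, at 908 and 870 CPM, were lower in replicate 2 (-1.02 and -0.67). The other 5 genes were higher, among them Mir455, the most abundant of the list at 3069 CPM (1.10). Mir802, which no other fixed list holds, was also higher, at 1.61 with 6 and 21 reads. Mir192 gained 38.4 CPM beside 68426 CPM for Mir122. A biological difference between the replicates was not tested.

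The spread of log2 ratios between the replicates, with an SD of 0.88 over 376 genes, followed hairpin GC content in part. The Spearman correlation across genes was 0.278, outside the range of -0.10 to 0.10 from shuffled values. It was 0.279 over genes with at least 100 reads, and lower, at 0.177, over the 176 genes with at least 1000 reads. The median log2 ratio ran from -0.39 at the lowest GC to 0.41 at the highest. Removing this trend, as a straight line, took away 4.55% of the variance (bootstrap range 1.13 to 9.62%). This argues against a linear trend with hairpin GC content as the main cause. GC content was taken over the whole hairpin, while inserts were below 30 bases, so that of the sequenced part was not tested. Neighbours in a cluster may differ together: the intraclass correlation of log2 ratios over 40 clusters was 0.186 (bootstrap range 0.040 to 0.330), above the shuffled limit of 0.175. With the GC trend removed it was 0.1955, above a limit of 0.171. Without chromosome 12 the correlation was 0.184, inside a shuffled range that widened to 0.237 with fewer genes. Outside chromosome 12, shared changes of neighbours therefore cannot be told apart from chance. Chromosome 12 was not tested alone.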
